A study of Mus musculus with 8 samples.

How the data were processed

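Gene expression was measured by RNA sequencing of ileal crypt cells from C57BL/6 mice. Crypts are the pockets at the base of the intestinal lining that hold its stem, Paneth and dividing cells. Per the labels' protocols, crypts were released from the ileum with EDTA and shaking, passed through a strainer and dissociated to single cells with trypsin, and total RNA was sequenced with standard Illumina libraries. The preparation included no sort, so other cells of the mucosa could be carried along. Mice received CPT-11 (irinotecan, a prodrug of a topoisomerase I inhibitor) at 20 mg per kg for 7 days, or vehicle. There were 4 libraries per group. The labels do not say that each library came from a separate mouse, so p-values measure the spread between these libraries, which may in part be technical.

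The deposited table holds estimated counts per gene, which the authors did not normalize. It has 56030 rows, and in each library between 10.3% and 11.1% of the values were not whole numbers, with a tolerance of 0. Per the submitters' processing notes, reads were handled with Bowtie2 2.4.1 and genome build GRCm38.p6. The tool that made the estimates, and whether it used strand, are not given in the sources used here. Estimated counts share reads between near-identical genes, so values within the alpha-defensin, Gsdmc, Ceacam1 and Ceacam2, and Ugt1a families are uncertain and were also summed per family. The table's 8 per-sample columns matched the samples by name, and the authors' group means were not used. The 543 rows with an identifier but no gene name were left out of library sizes and tests. They held between 0.325% and 0.662% of each library's count.

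Total counts per library ranged from 20790164 to 23479121. Counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3, using TMM scaling, the default expression filter (a count of about 10 in the smaller group and 15 in total), robust quasi-likelihood dispersions and the quasi-likelihood F test, two-sided. The filter kept 14011 genes. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. A second count also required a fold change above 2. CPM values were divided by the TMM-scaled library size. Standard errors of log2 fold changes were derived from the F statistic. Coordinates are those of GENCODE M21 on GRCm38, in which 55227 of the 55487 named rows were found by identifier. The table itself gives no coordinates or gene types.

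Before the data were examined, 32 gene lists were fixed: p53 targets, DNA repair, DNA replication, mitosis, crypt stem cells, regenerative epithelium, 5 epithelial lineages, antimicrobial defence, inflammasome, cytosolic DNA sensing, interferon-stimulated genes, MHC class I and class II, 7 lists of other cells, irinotecan handling, 4 metabolic and stress programs, and 3 lists for handling and RNA quality. Lists with at least 5 tested members were compared with all other genes by camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, and the adjustment ran over the 29 lists tested. Camera with an estimated correlation and fry, which tests the list's genes by themselves, were run beside it. The GO and KEGG terms that the table carries were tested by camera where 15 to 300 genes of a term were tested. The named genes follow a rule also fixed before the data were examined. It took the 10 largest rises and the 10 largest falls among genes with an adjusted p below 0.05, a mean log2 CPM above 1 and no overlap between the groups, leaving out predicted models, receptor segments and pseudogenes by the table. It added up to 4 members of each list with the smallest p, or 2 each way where members rose and fell. It also always took Cdkn1a, Mdm2, Mki67, Lgr5, Olfm4, Lyz1, Muc2, Reg3g, Aim2, Casp1, Il1b, Il18 and Top1. Other genes named, which are further members of those lists (such as Gsdmd, Nlrp6, Ugt1a1, Ugt1a6a, Ltf and Bpgm), the neighbour Ceacam1 and 3 genes of an added M cell list, were chosen after their values were seen.

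Alternatives fixed at the same time were RLE and upper-quartile scaling, no filter and a stricter filter (1 CPM in 4 libraries), DESeq2 1.42.0, limma-voom with and without quality weights, the replicate number as a block, and each library left out in turn. Protein-coding genes alone were to be tried only if the table gave a gene type, so that set was taken from GENCODE instead and counts as chosen after seeing the data. Also chosen after seeing the data were removal of each library's trend on gene length, leaving out CPT-11 replicates 2 and 4 together, inclusion of the unnamed rows, the summed families, camera with an estimated correlation on the terms, an M cell list, and an exact permutation test of each list's mean log2 CPM (pseudocount 0.5 CPM).

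On simulated counts for this comparison, with 14011 genes in the fit, the test recovered 3 of 67 genes changed 1.5-fold, 31 of 67 changed 2-fold and 63 of 66 changed 4-fold, with 0 false calls among 97. Small changes were therefore mostly beyond its reach. The simulation drew genes independently, with no library apart from the rest and no trend on gene length. Its rates, the 0 false calls included, need not hold for the real libraries. The lowest chi-square per degree of freedom between libraries of the same group was 22.3, so no pair of replicates agreed within sampling noise and all were counted.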

Results

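The data set compared ileal crypt cells of mice given CPT-11 with those of mice given vehicle, in 4 libraries each. The series is about chemotherapy, the AIM2 inflammasome and the ileal mucosa, and the comparison asks which crypt genes the drug course altered. Total counts were 20790164 to 23479121 per library, with 18979 to 20061 named genes detected. Within the vehicle group, libraries correlated at Spearman rho 0.987 to 0.990 across genes, which are not independent replicates. CPT-11 replicate 2 correlated at 0.931 to 0.962 with the other CPT-11 libraries, against 0.973 to 0.988 among those. It also held fewer reads from long genes than the other libraries, and CPT-11 replicate 4 shared this to a lesser degree.

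**Figure D1:**
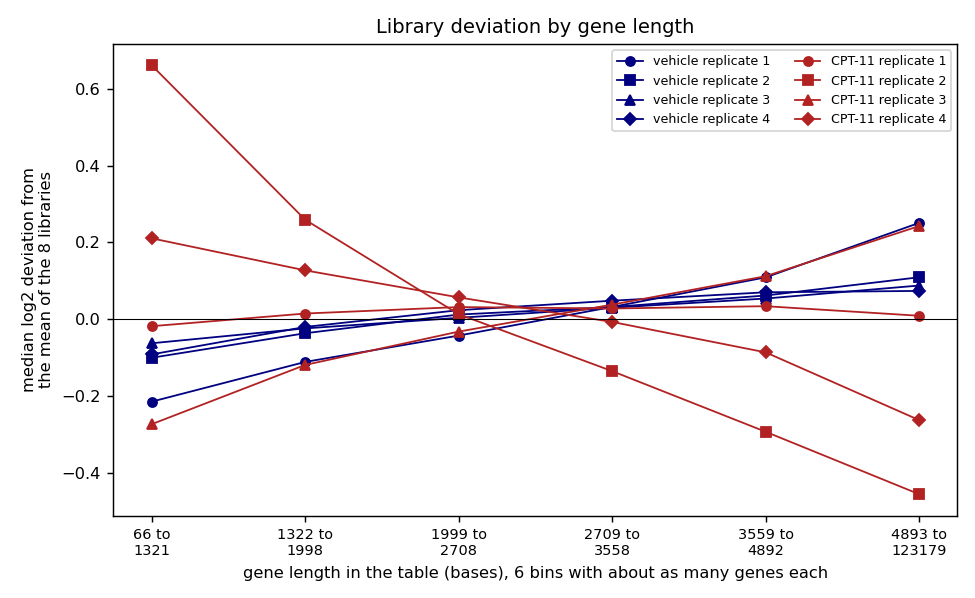
Median log2 deviation of each library from the mean of all 8, in 6 bins of gene length in bases, with vehicle libraries in dark blue, CPT-11 libraries in red and the symbol giving the replicate number. CPT-11 replicate 2 runs from 0.66 in the shortest genes to -0.46 in the longest, and CPT-11 replicate 4 from 0.21 to -0.26.

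The CPT-11 crypt preparations held more transcripts of p53 targets, glutathione enzymes, antimicrobial and oxidant defence genes and injury-associated epithelial genes. They held fewer of the gasdermin C family. Markers of enterocytes and of other mucosal cells were also higher in these unsorted preparations, as given below. A change per cell was therefore not told apart from a change in the mix of cells. Of 35 mitotic genes 18 were lower, and of 20 stem cell genes 5 were lower and 2 higher. Neither list passed camera with an estimated correlation (adjusted p = 0.123 and 0.169). Both passed by fry in 1 direction, which tests the list's genes by themselves (adjusted p = 0.00358 and 0.00837). Of 14011 genes tested, 770 changed, 417 upward and 353 downward, and 423 of these changed more than 2-fold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). Among the largest rises were Phlda3, a p53-induced inhibitor of Akt (27.7-fold, adjusted p = 9.26e-06), Il1rn, the interleukin 1 receptor antagonist (17.1-fold, adjusted p = 9.26e-06), Nox1, an epithelial NADPH oxidase (15.2-fold, adjusted p = 0.00129), and Gsta3, a glutathione transferase (10.5-fold, adjusted p = 7.67e-05). Atg9b (log2 fold change 4.52), Inka2 (4.20), Sval1 (3.45) and Slc25a48 (3.33) were also among them. Ceacam2 and Lrrc71 had the highest log2 fold changes, 7.25 ± 1.64 (SE) and 6.56 ± 1.52, but their level rested largely on CPT-11 replicate 2, without which they were 4.69 and 4.48. Lrrc71 had 5 counts in vehicle replicate 1 and 0 in the other vehicle libraries, so its fold change has no firm size, and without that library the fitted value was 9.95. Ceacam2 stood at 411 CPM in CPT-11 replicate 2, at 52.2 CPM in CPT-11 replicate 4 and at 3.18 to 4.04 CPM in the others of the group. Its near-identical neighbour Ceacam1 stood at 61.8 CPM in replicate 2 against 367 to 669 CPM in the others, and the 2 genes summed did not pass the test (log2 fold change 0.34, adjusted p = 0.244).

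The largest falls were in gasdermin C genes, which encode a pore-forming protein of the intestinal epithelium. Gsdmc4 fell from 100.2 ± 14.6 to 4.20 ± 1.20 CPM (mean ± SD, n = 4 each) and Gsdmc2 from 65.0 ± 3.68 to 3.66 ± 0.946 CPM. Gsdmc3 (log2 fold change -4.56) and Gsdmcl2 (-3.49), which GENCODE lists as a transcribed pseudogene, fell too. Reads can be split between these copies on chromosome 15, but the summed family also fell by 4.39 on the log2 scale (SE 0.24, adjusted p = 1.60e-05). Nrn1, Slc1a3, Dpysl5, Sfrp5, Dclk3 and Cbx6 made up the rest of the 10 largest falls, with log2 fold changes from -3.18 (Slc1a3) to -2.45 (Cbx6). Leaving out 1 library changed the number of genes called, to 240, 403, 236 and 416 without vehicle replicates 1 to 4 and to 392, 1177, 1522 and 477 without CPT-11 replicates 1 to 4. Those over 2-fold became 193 and 190 without vehicle replicates 1 and 3, and 693 without CPT-11 replicate 3. A fit with 1 library fewer can detect less, and the count fell whichever vehicle library was left out. A call lost in such a fit, here and below, need not mean that the result rested on that library. Among the genes named here, the calls of Ceacam2, Lrrc71 and Cbx6 were each lost without any 1 of vehicle replicates 1 to 4 or CPT-11 replicate 4, with adjusted p from 0.0578 to 0.118, from 0.0608 to 0.123 and from 0.0831 to 0.138. With no filter these genes were at 0.164, 0.164 and 0.177, and with limma-voom Ceacam2 and Lrrc71 were at 0.257 and 0.0738. Ceacam2 was at 0.152 with quality weights, and Cbx6 at 0.0506 with the stricter filter and 0.0524 with unnamed genes included. The call of Slc1a3 was lost without vehicle replicate 3 (0.0525).

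The p53 targets rose as a group. Of 31 tested, 16 rose and 0 fell, and 27 rose when adjusted over the list alone (median log2 fold change 0.87, camera adjusted p = 9.51e-37, and 0.00875 with an estimated correlation). Ephx1, a detoxifying epoxide hydrolase, went from 15.6 ± 1.63 to 105 ± 11.0 CPM, Ccng1, cyclin G1, rose 4.40-fold (adjusted p = 7.67e-05) and Zmat3, an RNA-binding protein, 3.73-fold (adjusted p = 0.00011). Cdkn1a, the p21 inhibitor of cyclin-dependent kinases, rose from 114 ± 16.8 to 254 ± 37.7 CPM (adjusted p = 0.00449). Mdm2, the p53 ubiquitin ligase, had a log2 fold change of 0.62 and did not pass (adjusted p = 0.0804), although it did in 5 of 21 alternatives (0.00234 to 0.227 over all of them), among them without CPT-11 replicate 4 (0.0381). Phlda3 lies at chromosome 1, 135766119 to 135769136, Ephx1 at chromosome 1, 180976210 to 181020904, and Cdkn1a at chromosome 17, 29090976 to 29100727 (GRCm38), and all are annotated as protein-coding. Top1, the drug's target, stood at 62.8 ± 6.18 CPM with vehicle and 67.9 ± 23.2 CPM with CPT-11 (log2 fold change 0.11, adjusted p = 0.790). Its sign turned without CPT-11 replicate 1 (-0.0058) or 3 (-0.037), it was 0.33 without CPT-11 replicate 2 and 0.18 and 0.063 without vehicle replicates 1 and 3, and it passed only without replicates 2 and 4 together (log2 fold change 0.45, adjusted p = 0.0359, against up to 0.990 in the other alternatives). Of 34 genes of DNA repair and topoisomerase I damage, 0 rose and 0 fell by edgeR, or 6 fell when adjusted over the list alone. At an unadjusted p below 0.05, 0 rose and 15 fell, and DESeq2 called 6 falls. The median was -0.43 (camera adjusted p = 4.20e-05, but 0.351 with an estimated correlation). Fanci had the smallest p (log2 fold change -0.64, adjusted p = 0.0521), and Fancd2 was at -0.97 (adjusted p = 0.0603). Both passed without CPT-11 replicate 2 (0.0453 and 0.0237) or 3 (0.0433 and 0.0388), and ranged up to 0.142 and 0.178 over the alternatives. Without those replicates 4 and 3 members of the list fell, and the median was -0.27 without replicate 2.

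Mitotic genes were lower, and dilution by other cells was not tested for them. Of 35, 18 fell and 0 rose, and 28 fell when adjusted over the list alone, but 8 and 9 fell over all genes without vehicle replicates 1 and 3 (median -0.71, camera adjusted p = 1.63e-21, but 0.123 with an estimated correlation). Racgap1, needed for cytokinesis, fell from 70.4 ± 4.75 to 33.5 ± 3.89 CPM (adjusted p = 0.00179) and the kinase gene Aurkb from 40.1 ± 4.66 to 18.8 ± 1.75 CPM (adjusted p = 0.00216). Plk1 (log2 fold change -0.94) and Nusap1 (-1.14) fell too. Mki67, a marker of dividing cells, fell from 142 ± 33.5 to 62.5 ± 21.6 CPM (adjusted p = 0.0296), a call lost without vehicle replicate 1, 3 or 4 or CPT-11 replicate 1 or 4 (adjusted p 0.0610 to 0.0948). Of 35 genes of DNA replication, only Pole, the catalytic subunit of DNA polymerase epsilon, fell over all genes (log2 fold change -0.79, adjusted p = 0.0412), a call lost without any 1 vehicle replicate or CPT-11 replicate 1 or 4 (0.0615 to 0.137) and without CPT-11 replicates 2 and 4 (0.0716). When adjusted over the list alone, 5 fell. The list's median was -0.19 (camera adjusted p = 0.00279, but 0.555 with an estimated correlation), and 0 members fell without any 1 vehicle replicate or CPT-11 replicate 1, but 3, 2 and 2 without CPT-11 replicates 2, 3 and 4. The median was -0.12 without CPT-11 replicate 2 and -0.35 without replicate 4. Cdc45 (log2 fold change -0.60, adjusted p = 0.0525) and Pola1 (15.6 ± 2.09 to 7.75 ± 2.66 CPM, adjusted p = 0.0557) did not pass, though Cdc45 did without CPT-11 replicate 4 (0.0483) and Pola1 without replicate 2 (0.0102) or 3 (0.0443). Over the alternatives they ranged from 0.00518 to 0.163 and from 0.00198 to 0.158.

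Among 20 genes of crypt base stem cells, 5 fell and 2 rose, over all genes and adjusted over the list alone (median -0.37, camera adjusted p = 6.11e-07, but 0.169 with an estimated correlation). Lgr5, the R-spondin receptor that marks these cells (chromosome 10, 115450311 to 115587780), fell from 12.4 ± 0.801 to 2.98 ± 0.187 CPM (adjusted p = 7.92e-05). Olfm4, a secreted stem cell marker (chromosome 14, 79984081 to 80023139), fell from 1236 ± 103 to 356 ± 62.5 CPM (adjusted p = 0.000782). Nrn1 fell from 15.1 ± 1.97 to 1.81 ± 0.365 CPM. Against these, Igfbp4 (log2 fold change 0.79, adjusted p = 0.0129) and Msi1 (0.74, adjusted p = 0.0349) rose. The call of Igfbp4 was lost without vehicle replicate 3 (0.0609) and that of Msi1 without any 1 vehicle replicate or CPT-11 replicate 1 or 4 (0.0665 to 0.123) and with no filter (0.0687). Of the rises, 0 were called without vehicle replicate 3, and 1 without vehicle replicate 1, 2 or 4 or CPT-11 replicate 1 or 4. The list's median was -0.22 without CPT-11 replicate 2.

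Of 23 genes of regenerative and fetal-like epithelium, a state of the gut lining after injury, 9 rose and 0 fell, and 16 rose when adjusted over the list alone. Without vehicle replicate 1 or 3, 5 rose (median 1.02, camera adjusted p = 5.93e-18, and 0.00875 with an estimated correlation). Besides Il1rn, these included Areg, an EGF receptor ligand (8.36-fold, adjusted p = 0.00129), Cd44 (2.36-fold, adjusted p = 0.00123) and Plaur, the urokinase receptor (2.93-fold, adjusted p = 0.00743). Il1rn, Plaur and Cd44 are also expressed by myeloid cells, and markers of macrophages and dendritic cells and of dissociation stress were higher in the same libraries (medians 0.95 and 0.52, adjusted p = 0.169 and 0.123 with an estimated correlation). Of 26 genes of epithelial antimicrobial and inflammatory defence, 13 rose and 1 fell, or 18 and 2 when adjusted over the list alone, and 8 rose without vehicle replicate 3 (median 1.41, camera adjusted p = 2.96e-14, and 0.00362 with an estimated correlation). Reg3g, an antibacterial lectin, rose from 243 ± 75.9 to 1216 ± 434 CPM (adjusted p = 0.00449). The chemokine gene Cxcl16 rose 4.42-fold (adjusted p = 0.00129), as did Nox1, given above. Reg1, of the same family as Reg3g, fell from 6.83 ± 2.60 to 2.06 ± 0.707 CPM (adjusted p = 0.0203), a call lost without vehicle replicate 1, 2 or 3 or CPT-11 replicate 1 (0.0551 to 0.0729).

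**Figure D2:**
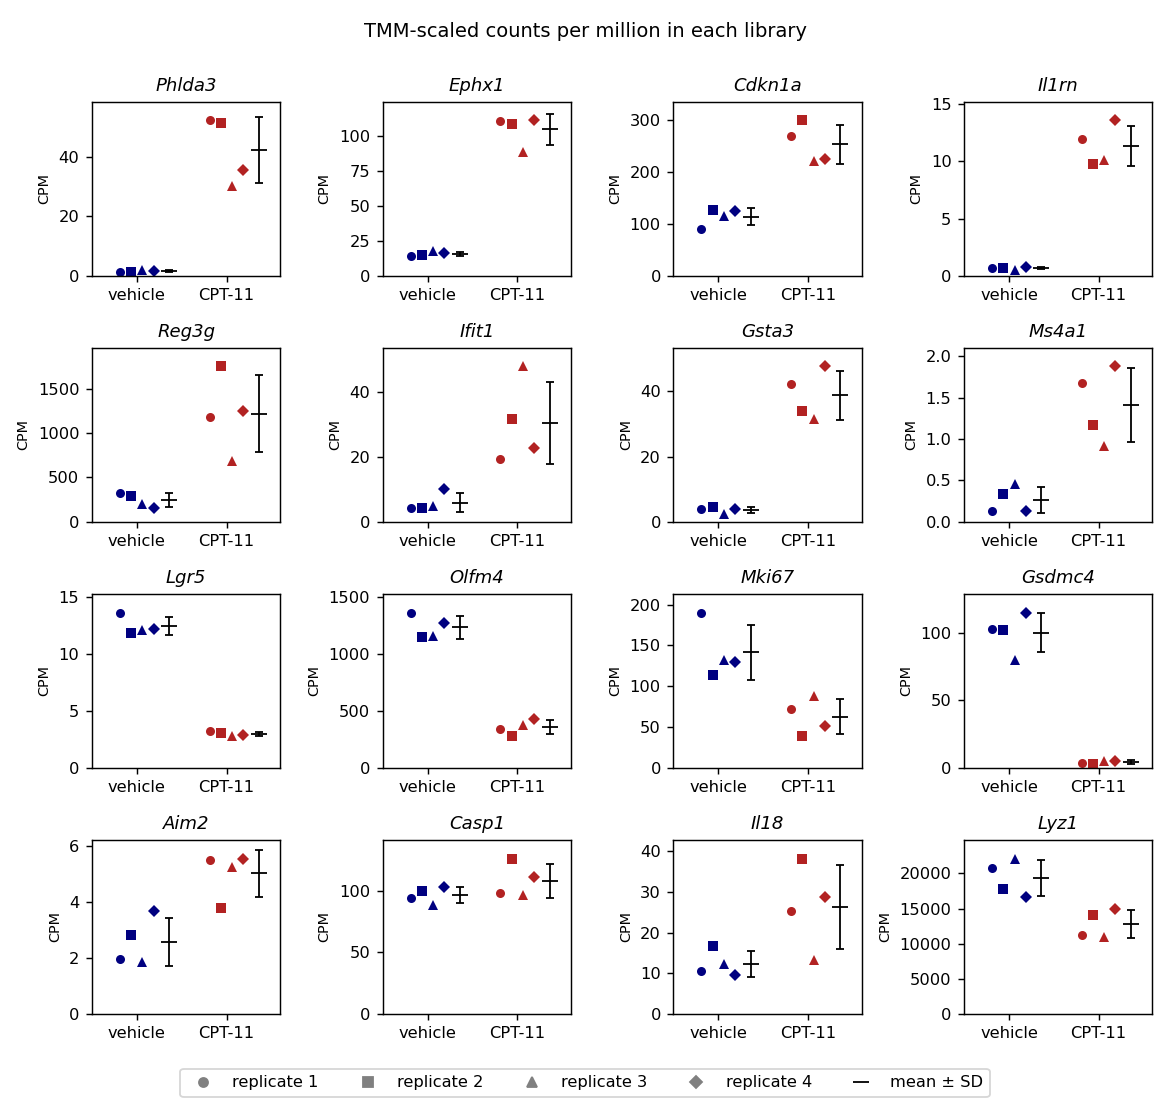
TMM-scaled CPM (linear axes from 0) of 16 genes in each library, vehicle in dark blue and CPT-11 in red, the symbol giving the replicate number and the bar the group mean ± SD (n = 4). Lgr5, Olfm4 and Gsdmc4 do not overlap between the groups, while Casp1 does (96.5 ± 6.65 and 108 ± 13.7 CPM).

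The inflammasome and pyroptosis list moved in both directions. Of 22 tested members, 3 rose and 4 fell, or 7 and 4 when adjusted over the list alone. The list as a whole did not pass (camera adjusted p = 0.427), and its median of 0.19 had the opposite sign to its mean of -0.15 and to the direction of the test. The members that rose were Il1rn, Casp4, the sensor caspase for cytosolic lipopolysaccharide (8.24 ± 1.74 to 26.4 ± 7.57 CPM, adjusted p = 0.00449), and Gsdmd, the pore-forming target of inflammatory caspases. Those that fell were Gsdmc2, Gsdmc3, Gsdmc4 and Nlrp6. The call of Gsdmd was lost without vehicle replicate 1, 3 or 4 (0.0628 to 0.0927) and that of Nlrp6 without any 1 vehicle replicate or CPT-11 replicate 1 or 4 (0.0722 to 0.120). Without CPT-11 replicate 2, 5 members rose. The list passed without that replicate (adjusted p = 0.0338, median 0.13) and without CPT-11 replicates 2 and 4 (0.0198, median 0.13). It also passed with the near-identical families summed (0.00022, median 0.33), in a range up to 0.866 over the alternatives. That sum removes Gsdmc2, Gsdmc3 and Gsdmc4, which fell, as separate members of the list. With all members, the list's mean log2 CPM was lower in every CPT-11 library (4.78 to 4.88) than in any vehicle library (4.92 to 5.14). Of the members, 14 had a positive fold change and 8 a negative one, so the lower mean does not describe most of them. Aim2, the DNA sensor named in the series title (chromosome 1, 173350879 to 173466040), stood at 2.57 ± 0.849 CPM with vehicle and 5.01 ± 0.840 CPM with CPT-11. Its log2 fold change of 0.97 ± 0.27 (SE) did not pass (adjusted p = 0.0646), and it passed in 7 of 21 alternatives (0.00346 to 0.184 over all of them), among them without CPT-11 replicate 2 (0.0249) and without vehicle replicate 4 (0.0478). Il18 was at 12.3 ± 3.16 and 26.4 ± 10.4 CPM (log2 fold change 1.10, adjusted p = 0.0655, passing in 3 of 21 alternatives, among them at 0.0133 without CPT-11 replicate 3, with a range from 0.00802 to 0.239). Casp1 had a log2 fold change of 0.17 (adjusted p = 0.429), with the sign turned once the trend on gene length was removed (-0.0055) and 0.094 without CPT-11 replicate 2. Il1b had between 0 and 17 counts per library and was below the expression filter, so a difference was not detectable at this depth.

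Of 15 genes of cytosolic DNA sensing through cGAS and STING, 0 rose and 0 fell by edgeR, or 2 rose when adjusted over the list alone, as many as at an unadjusted p below 0.05 and by DESeq2 (median 0.20, camera adjusted p = 0.142). The list passed without vehicle replicate 4 (0.00921) and with no filter on low counts (0.0198), in a range up to 0.337 over the alternatives. Its median was 0.12 and 0.11 without vehicle replicates 1 and 2. Zbp1 had the smallest p (log2 fold change 1.10, adjusted p = 0.0724) and passed without vehicle replicate 4 (0.0210), in a range from 0.0109 to 0.252. Among 46 interferon-stimulated genes, 8 rose and 0 fell, and 27 rose when adjusted over the list alone. Over all genes the rises became 1, 3, 1 and 22 without vehicle replicates 1 to 4 and 4 without CPT-11 replicate 1. All 46 fold changes were positive (mean log2 fold change 0.98, camera adjusted p = 3.80e-15, but 0.253 with an estimated correlation). Their mean was 3.60 log2 CPM in vehicle replicate 4, against 2.51 to 2.72 in the other vehicle libraries and 3.63 to 4.09 in the CPT-11 libraries. Ifit1 rose from 5.84 ± 2.92 to 30.4 ± 12.8 CPM (adjusted p = 0.00818, but 0.0572 without CPT-11 replicates 2 and 4) and Ifit3 4.70-fold (adjusted p = 0.0127), the latter call lost without vehicle replicate 1 (0.0524) or 3 (0.0558). Oasl1 rose 3.10-fold (adjusted p = 0.0190), a call lost without vehicle replicate 1, 2 or 3 (up to 0.0775) and without CPT-11 replicates 2 and 4 (0.0797). For MHC class I presentation, 0 of 24 genes rose or fell by edgeR, over all genes or adjusted over the list alone, while 7 were higher at an unadjusted p below 0.05 and DESeq2 called 3 rises. The list had a median of 0.28 (camera adjusted p = 0.0119, but 0.454 with an estimated correlation and 0.0976 by fry in 1 direction). It was at 0.0564 without vehicle replicate 2 and at 0.0730 with the trend on gene length removed. The latter was the highest of the 21 alternatives, which started at 0.00115. For MHC class II, 0 of 12 passed over all genes by edgeR, and 4 rose when adjusted over the list alone. At an unadjusted p below 0.05, 5 were higher, DESeq2 called 4 rises, and 2 rose without CPT-11 replicate 2 or 3 (median 1.04, camera adjusted p = 0.00028, but 0.411 with an estimated correlation). The median was 0.53 without CPT-11 replicate 2. Markers of B cells and of macrophages and dendritic cells, which carry class II molecules themselves, were higher as well (medians 1.52 and 0.95, adjusted p = 0.169 each with an estimated correlation). H2-Aa stood at 28.7 ± 15.1 and 85.0 ± 41.3 CPM (adjusted p = 0.0624, and 0.0484 without CPT-11 replicate 3, in a range from 0.00356 to 0.265).

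Of 24 Paneth cell genes only Pnliprp2, a lipase, fell (446 ± 70.2 to 225 ± 48.8 CPM, adjusted p = 0.0170), a call lost without vehicle replicate 1 (0.0636) or 3 (0.0638). The same 1 gene fell when adjusted over the list alone, and the median was -0.28 (camera adjusted p = 0.00666, but 0.614 with an estimated correlation, 0.0688 without CPT-11 replicate 1 and 0.181 without CPT-11 replicate 3). The number that fell was 0 without vehicle replicate 1 or 3, 8 without CPT-11 replicate 2, 16 without CPT-11 replicates 2 and 4 and 11 with the trend on gene length removed. The median was -0.50 without CPT-11 replicate 2 and -0.15 without CPT-11 replicate 3. Lyz1, lysozyme, stood at 19358 ± 2553 and 12828 ± 1990 CPM (log2 fold change -0.59, adjusted p = 0.146, and 0.0179 without replicates 2 and 4, passing in 4 of 21 alternatives in a range from 0.00611 to 0.332). The summed alpha-defensins did not pass (log2 fold change -0.19, adjusted p = 0.770). Of 23 goblet cell genes 1 rose, over all genes and adjusted over the list alone, namely Fut2, a fucosyltransferase (0.853 ± 0.278 to 3.25 ± 0.759 CPM, adjusted p = 0.00914). The goblet list did not pass (camera adjusted p = 0.616), and its median of 0.10 became -0.068 without CPT-11 replicate 2. It was 0.049 and 0.17 without vehicle replicates 3 and 4, and 0.24, 0.23 and 0.026 without CPT-11 replicates 1, 3 and 4. Without CPT-11 replicates 2 and 4 its median was -0.32 and it passed downward (0.000416, the lowest of the alternatives, up to 0.791). Muc2 was at 792 ± 178 and 1554 ± 1098 CPM (log2 fold change 0.97, adjusted p = 0.189, and 0.38 without CPT-11 replicate 2 or 0.065 without CPT-11 replicates 2 and 4). Neither the 28 enteroendocrine genes (camera adjusted p = 0.182) nor the 21 tuft cell genes (0.643) passed, with 0 members called by edgeR in either list over all genes or adjusted over the list alone. At an unadjusted p below 0.05, 8 enteroendocrine genes were higher and 3 lower (DESeq2 called 5 rises and 1 fall), and 1 tuft cell gene was higher and 3 lower (DESeq2 called 1 fall). Enteroendocrine genes had 4 rises and a median of 0.31 without CPT-11 replicate 3, and 1 rise and 1 fall without CPT-11 replicate 2, when the median was -0.042. The tuft cell median of 0.02 and the direction of its test differed in sign, and the median was negative without vehicle replicate 1, 3 or 4 or any 1 CPT-11 replicate but the third (-0.093 to -0.032), and 0.17 and 0.11 without vehicle replicate 2 and CPT-11 replicate 3. Absorptive enterocyte genes were higher, with 3 of 35 up and 0 down over all genes and adjusted over the list alone, though 0 rose without vehicle replicate 1, 2 or 3 and 1 without CPT-11 replicate 1 or 4 (median 0.55, camera adjusted p = 4.74e-07, but 0.424 with an estimated correlation). Slc10a2, the ileal bile acid transporter, rose from 9.77 ± 7.58 to 50.6 ± 13.9 CPM (adjusted p = 0.0192), and Fabp2, a fatty acid binding protein, from 2374 ± 563 to 9161 ± 6651 CPM (adjusted p = 0.0337). The first call was lost without vehicle replicate 1, 2 or 3 or CPT-11 replicate 4 (0.0540 to 0.0735), with no filter on low counts (0.0893) and without CPT-11 replicates 2 and 4 (0.166), and the second without any 1 vehicle replicate or CPT-11 replicate 1 (0.0574 to 0.120). Slc51b, a subunit of the basolateral bile acid transporter, also rose (log2 fold change 1.08, adjusted p = 0.0493), a call lost without vehicle replicate 1, 2 or 3 or CPT-11 replicate 1 or 4 (0.0764 to 0.158), without CPT-11 replicates 2 and 4 (0.0771) and with unnamed genes included (0.0510).

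Markers of other mucosal cells were also higher. Of 20 B cell and plasma cell genes, 7 rose and 0 fell, and 13 rose when adjusted over the list alone (median 1.52, camera adjusted p = 1.94e-07, but 0.169 with an estimated correlation). Their levels were low. Ms4a1, which encodes CD20, went from 0.262 ± 0.162 to 1.41 ± 0.443 CPM (adjusted p = 0.0195, lost without vehicle replicate 1 or 4 or CPT-11 replicate 1 or 4, 0.0551 to 0.0735), and Cd22 from 0.289 ± 0.227 to 1.84 ± 0.403 CPM (adjusted p = 0.0172, and 0.0641 without vehicle replicate 1). The list had 0, 2 and 1 rises without vehicle replicates 1, 2 and 4, and 2, 12 and 1 without CPT-11 replicates 1, 2 and 4. Without CPT-11 replicates 2 and 4 together it had 3. Of 15 genes of macrophages and dendritic cells, 3 rose and 0 fell, or 8 rose and 1 fell when adjusted over the list alone. Without vehicle replicate 1, 3 or 4 or CPT-11 replicate 1 or 4 only 1 rose, and without CPT-11 replicate 3, 6 did (median 0.95, camera adjusted p = 0.000471, but 0.169 with an estimated correlation). Cd14, a co-receptor for lipopolysaccharide, rose 2.49-fold (adjusted p = 0.00658), and C1qc 2.56-fold (adjusted p = 0.0445, lost without any 1 vehicle replicate or CPT-11 replicate 1 or 4, 0.0609 to 0.110, and without CPT-11 replicates 2 and 4, 0.108). Of 30 T cell and intraepithelial lymphocyte genes, 0 rose or fell by edgeR on either adjustment, 7 were higher at an unadjusted p below 0.05, DESeq2 called 2 rises, and 3 rose without CPT-11 replicate 3 (median 0.31, camera adjusted p = 0.0131, but 0.630 with an estimated correlation). That list failed the test without vehicle replicate 1 (0.114), vehicle replicate 2 (0.338) or CPT-11 replicate 2 (0.0704), without CPT-11 replicates 2 and 4 (0.305), with DESeq2 (0.0976), with the length trend removed (0.0562) and over protein-coding genes (0.0636), while the lowest of the alternatives was 1.05e-06. Its median was 0.15, 0.13 and 0.72 without vehicle replicates 1, 2 and 4. Of 15 genes of fibroblasts, muscle and endothelium, 0 rose or fell by edgeR on either adjustment, 6 were higher at an unadjusted p below 0.05 and DESeq2 called 1 rise. Their median was 0.82 (camera adjusted p = 0.0218, but 0.555 with an estimated correlation, 0.0623 without vehicle replicate 1, 0.181 without CPT-11 replicate 3 and 0.325 with no filter, with 0.000681 the lowest of the alternatives). It was 1.35 without vehicle replicate 2 and 0.54 without CPT-11 replicate 3. Neutrophil and mast cell, red blood cell and pancreatic acinar lists had 4, 4 and 2 tested members and got values only, with medians of 0.88, 0.92 and -0.19. In the first, Ltf, lactoferrin, rose from 0.184 ± 0.0710 to 3.45 ± 0.527 CPM (adjusted p = 0.000198), and in the second Bpgm rose 1.47-fold (adjusted p = 0.0222, lost without any 1 vehicle replicate or CPT-11 replicate 1, 0.0540 to 0.0890, and with no filter, 0.0523). Genes of dissociation stress and the immediate-early response were higher too, with 7 of 28 up and 0 down, or 11 up when adjusted over the list alone. The rises became 2, 4, 1 and 1 without vehicle replicates 1 to 4 and 3 without CPT-11 replicate 1 or 4 (median 0.52, camera adjusted p = 7.01e-07, but 0.123 with an estimated correlation). Hspa1b, a heat shock protein, rose from 9.82 ± 2.54 to 42.5 ± 23.9 CPM (adjusted p = 0.0116). The 13 mitochondrially encoded genes had a median of 0.62, with 0 called by edgeR on either adjustment, 5 higher at an unadjusted p below 0.05 and 1 rise by DESeq2 (camera adjusted p = 0.0140, but 0.454 with an estimated correlation, 0.0562 with the length trend removed and 0.0518 without CPT-11 replicates 2 and 4, in a range from 0.00246). The median was 0.32 without CPT-11 replicate 2. The 41 ribosomal protein genes had a median of 0.20, with 0 called by edgeR on either adjustment, 1 higher at an unadjusted p below 0.05 and 1 rise by DESeq2. They did not pass (0.134), but did upward without vehicle replicate 3 (0.0489), CPT-11 replicate 1 (0.0353) or CPT-11 replicate 3 (0.000365). Their median was -0.0040 without CPT-11 replicate 2 and 0.36 without CPT-11 replicate 3, and without CPT-11 replicates 2 and 4 it was -0.23 and they passed downward (6.56e-05, up to 0.801 over the alternatives).

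Of 28 genes of NRF2 and glutathione, 11 rose and 0 fell, and 17 rose when adjusted over the list alone. The rises became 6 without vehicle replicate 1 or 3 and 7 without vehicle replicate 4 (median 0.65, camera adjusted p = 5.78e-20, and 0.00875 with an estimated correlation). Gsta3 went from 3.69 ± 0.947 to 38.8 ± 7.47 CPM and Akr1b8, an aldo-keto reductase, from 3.46 ± 0.590 to 29.8 ± 6.39 CPM (adjusted p = 6.17e-05). Ephx1 stands both here and among the p53 targets. Genes of irinotecan activation, glucuronidation and transport went both ways, with 5 of 31 up and 3 down, or 8 and 3 when adjusted over the list alone, and the list did not pass (median 0.29, camera adjusted p = 0.126). It did without vehicle replicate 2 (0.0111) or CPT-11 replicate 4 (0.0247), in a range up to 0.604 over the alternatives. Its median was 0.15 and 0.18 without CPT-11 replicates 2 and 3. Its rises became 3 without vehicle replicate 1, 3 or 4 or CPT-11 replicate 1, and its falls 1 without vehicle replicate 1. The carboxylesterases Ces1g and Ces1f rose (6.97-fold, adjusted p = 0.00192, and 2.90-fold, adjusted p = 0.00358). The uptake transporter Slco2b1 fell from 49.6 ± 7.76 to 18.9 ± 4.45 CPM (adjusted p = 0.00453), and Ces1d from 10.9 ± 2.18 to 4.91 ± 0.856 CPM (adjusted p = 0.0120, and 0.0513 without vehicle replicate 1). Ugt1a6a rose (log2 fold change 1.52) and Ugt1a1 fell (-1.02, a call lost without any 1 vehicle replicate or CPT-11 replicate 1 or 4, adjusted p 0.0628 to 0.108), but these genes share exons, and the summed Ugt1a family did not pass (log2 fold change -0.42, adjusted p = 0.116). Of 23 cholesterol synthesis genes, 4 rose and 0 fell, or 5 rose when adjusted over the list alone (median 0.31, camera adjusted p = 0.00666, but 0.308 with an estimated correlation). Msmo1 (1.78-fold, adjusted p = 0.0195) and Sqle, squalene epoxidase (1.63-fold, adjusted p = 0.0297), were among them. The first call was lost without vehicle replicate 1, 2 or 3 or CPT-11 replicate 1 or 4 (0.0546 to 0.0816) and the second without these or vehicle replicate 4 (0.0641 to 0.106). The rises of the list became 0 without vehicle replicate 1, 2 or 3 or CPT-11 replicate 1 or 4, 1 without vehicle replicate 4 and 7 without CPT-11 replicate 3. Of 23 genes of fatty acid oxidation, 3 rose and 0 fell, or 4 rose and 1 fell when adjusted over the list alone, and the list did not pass (median 0.08, camera adjusted p = 0.210). The rises became 0 and 1 without vehicle replicates 1 and 3. The median was 0.035 and 0.12 without vehicle replicates 1 and 2, and 0.14, 0.0078 and 0.049 without CPT-11 replicates 1, 3 and 4. Acaa1b, a peroxisomal thiolase, rose 3.29-fold (adjusted p = 0.0126, and 0.0515 without vehicle replicate 1). The unfolded protein response list did not pass (median 0.10, camera adjusted p = 0.0916) except without vehicle replicate 1 (0.0359), in a range up to 0.345. Its median was 0.16 without that library and 0.15 without CPT-11 replicate 2. Of its 26 genes 1 rose on either adjustment, Sesn2, which is also a p53 target. This call was lost without any 1 vehicle replicate or CPT-11 replicate 1 (0.0700 to 0.0923), and 2 rose without CPT-11 replicate 2 or 3.

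**Figure D3:**
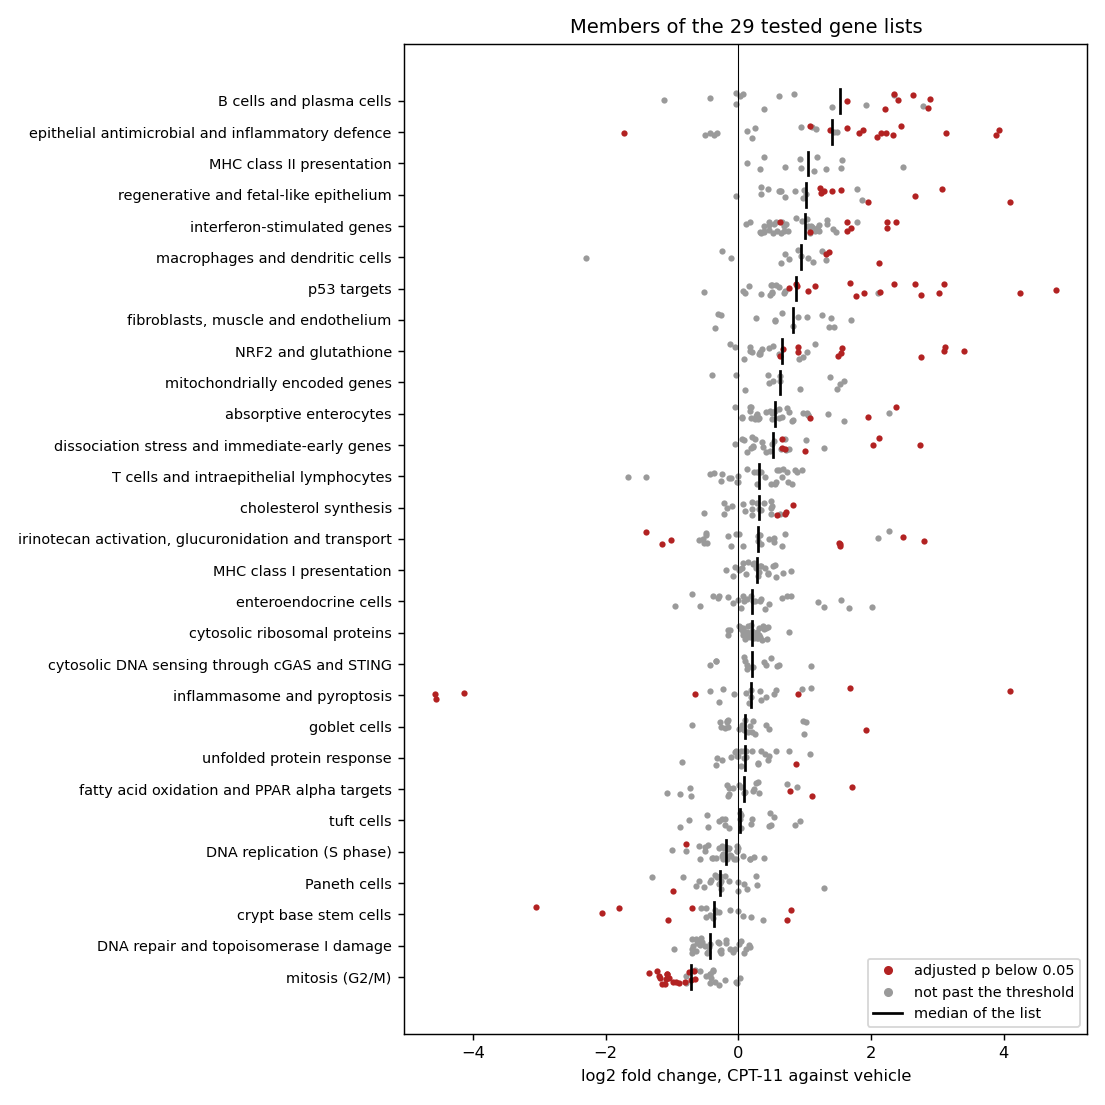
Log2 fold change, CPT-11 against vehicle, of each tested member (point) of the 29 tested lists, red where the adjusted p is below 0.05 and grey otherwise, with a bar at the list's median and vertical scatter only to part the points. The p53 targets reach 4.79 with 16 members past the threshold, and 18 of 35 mitotic genes pass on the left.

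In all, 20 of the 29 lists passed with the preset correlation, 15 upward and 5 downward, and 4 with an estimated correlation, namely p53 targets, regenerative epithelium, antimicrobial defence, and NRF2 and glutathione. The preset correlation can call lists on any grouping that follows a difference between libraries, and 4 of the 35 splits of the 8 libraries, the real one included, gave at least 20 lists. Of 2609 annotation terms tested, 133 passed, 70 upward and 63 downward. The smallest p belonged to the kinesin complex, in which 12 of 40 genes fell and 0 rose (camera adjusted p = 7.62e-06), followed by the classical pathway of complement activation, in which 6 of 29 rose (3.11e-05), and cytokine activity, in which 11 of 89 rose and 1 fell (3.11e-05). With an estimated correlation 0 terms passed, these included (adjusted p = 0.941 each, unadjusted 0.0403, 0.0166 and 0.0299), and 37 of the 133 had an unadjusted p below 0.05. Without CPT-11 replicate 3, 241 terms passed with the preset correlation.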

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

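The tests of a wrong label, of dilution by villus cells and of lymphocytes of every kind were chosen only after the related result was seen. Within groups of 4 libraries, 346 sets of values were examined for a library far from the rest, using the ratio of its gap to the whole range. Of these 22 stood out, where chance would give about 17.3, so the number is not far from chance.

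Of these, 6 came from CPT-11 replicate 2. It was the lowest of its group for Aim2 (2.09 log2 CPM, the next at 2.52, ratio 0.851) and Pola1 (ratio 0.946), and the highest for B2m (0.878), H2-Aa (0.871), Ctss (0.900) and the mean of the MHC class II list (0.835). CPT-11 replicate 3 was lowest for Ephx1 (0.911), H2-Ob (0.924), Msmo1 (0.880) and Sqle (0.916) and highest for Ifit1bl1 (0.910) and the fatty acid oxidation list (0.915). CPT-11 replicate 1 was highest for Ccng1 (0.937) and the mitosis list (0.859) and lowest for Hspb1 (0.915). Vehicle replicate 1 was highest for Lrrc71, where the other vehicle libraries had no count (ratio 1), and for Mptx1 (0.885), and lowest for Rpl10 (0.917). Vehicle replicate 3 was lowest for Il1rn (0.887) and Pou2f3 (0.965), and vehicle replicate 4 highest for Slc25a48 (0.918) and Ifit3 (0.888).

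Rows without a gene name, which the comparison leaves out, were also tested. With them included, 14 of 287 tested rose with CPT-11 and 3 fell. Over all genes in this setting there were 398 rises and 335 falls among 14298. The share that rose was thus larger among the unnamed rows and the share that fell smaller, a difference that was not tested. The unnamed rows held 0.581 ± 0.0594% of counts with vehicle and 0.426 ± 0.0893% with CPT-11 (mean ± SD, n = 4 each).

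The whole CPT-11 replicate 2 library stood apart. The spread over genes of its deviation from the other 7 was 1.81 times the largest such spread among those. Removing each library's trend on gene length left the ratio at 1.75, and removing the trend on GC content left it at 1.81, both above the limit of 1.5 set beforehand, so neither trend by itself accounts for the library, although reads from long genes were lower in it. A vehicle library with the wrong label is argued against by its mean over the p53 targets of 4.68 log2 CPM, against 3.43 to 3.54 in vehicle libraries. Its TMM factor was 0.731, against 0.977 to 1.10 in the others. Among the CPT-11 libraries it had the highest mean of the Paneth (9.88 log2 CPM), goblet (7.37), enteroendocrine (4.17) and enterocyte lists (9.14). Its mean of the stem cell list was the lowest (4.31). A difference in RNA quality, in library preparation, in the mix of cells or in the response to the drug in that sample stays open and was not tested.

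The fall of Lgr5 and Olfm4 could come from more villus cells in the CPT-11 preparations, since enterocyte genes were higher. Paneth cells share the crypt base, and their list had a median log2 fold change of -0.28 (SD over members 0.50), or -0.79 without CPT-11 replicates 2 and 4, both above the smaller fall of -1.79. With the trend on gene length removed, Lgr5 (4714 bases) kept 0.927 of its fall and Olfm4 (1640 bases) 1.075. Genes of 1322 to 1998 bases were raised in CPT-11 replicates 2 and 4 (medians 0.26 and 0.13). Removing the trend could therefore hardly shrink the fall of Olfm4. For these 2 genes dilution alone is thus argued against, and for Lgr5 also a loss of reads from long genes. For the stem cell list as a whole the comparison with Paneth genes cannot decide. The stem cell median was -0.37, or -0.16 without CPT-11 replicates 2 and 4, where the Paneth list fell further. A lower level of Lgr5 and Olfm4 transcripts with CPT-11 is a hypothesis found and tested on the same data. A change in the number of Paneth cells was not tested and would alter the first comparison.

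The higher B cell markers may reflect more lymphoid follicles in the CPT-11 preparations. A list of 8 M cell genes, the cells that cover such follicles, written before its values were seen, was higher (median log2 fold change 0.23, against 1.52 for B cells, camera p = 0.00451, and 0.0525 with an estimated correlation), with Marcksl1 and Anxa5 up among 7 tested, but its most specific member, Gp2, had a log2 fold change of -0.22 (adjusted p = 0.822), which was 0.052 and 0.065 without vehicle replicates 2 and 4 and -0.72 without CPT-11 replicate 1. Marcksl1 (21.8 and 47.8 CPM) and Anxa5 (14.8 and 24.5 CPM) are expressed widely, and the call of Anxa5 was lost without vehicle replicate 1 or 3 or CPT-11 replicate 1 or 4 (adjusted p 0.0503 to 0.0773), so the test is weak. A rise of lymphocytes of every kind remained open, because the difference between the B and T cell list means was -1.98 ± 0.628 log2 CPM with vehicle and -1.57 ± 0.196 with CPT-11 (exact permutation p = 0.286, two-sided). A change in B cells with treatment is open too.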

How the results depend on the processing

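The settings that remove each library's trend on gene length, leave out CPT-11 replicates 2 and 4, keep protein-coding genes by GENCODE, include unnamed genes, sum near-identical families and estimate the correlation for annotation terms were chosen after seeing the data. Of 83 called genes named by the rule or besides it, 0 changed sign in any of the 21 alternatives that tested them, 43 kept their call in all of those and 40 lost it in at least 1, of which 27 lost it only when samples were left out. Some genes were not tested in all 21. All of the 770 called genes that were tested in an alternative kept their direction there. Of the 770, 762 did not overlap between the groups, so a turn of sign was unlikely from the start. Scaling by RLE (780 genes) or upper quartile (753) shifted the median of all genes by at most 0.0060 on the log2 scale. The count was 791 with no filter, 736 with the stricter one, 788 with limma-voom, 812 over protein-coding genes, 733 with unnamed genes included and 764 with families summed. Over all alternatives, named genes kept sign and side of the threshold in 2658 values, gained a call in 180 and lost one in 191, and lists did so in 612, 18 and 44. At this depth and number of libraries, 3 of 67 simulated 1.5-fold changes were recovered.

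DESeq2 called 1884 genes (1045 up, 839 down, 717 over 2-fold) and limma-voom with quality weights 3170 (1535 up, 1635 down, 723 over 2-fold). With the length trend removed there were 1294, of which 684 were down, and 47.1% of calls were upward against 54.2% before. Without CPT-11 replicates 2 and 4 there were 1212 (637 up, 575 down). With 1 library left out, the range was 236 to 1522 genes changed, 132 to 769 up, 104 to 753 down, 190 to 693 over 2-fold and 95 to 241 annotation terms. Of the 29 lists, 4 passed by camera with an estimated correlation and 12 by fry in 1 direction. Besides those 4, fry passed mitosis (adjusted p = 0.00358), stem cells (0.00837), B cells (0.00837), dissociation stress (0.00601) and macrophages and dendritic cells (0.0126). It also passed DNA repair (0.0302), interferon-stimulated genes (0.0300) and cholesterol synthesis (0.0302). By fry in either direction 23 passed, among them the inflammasome and irinotecan lists (adjusted p = 4.55e-07 each), whose members went both ways. Of the terms 0 passed with an estimated correlation (lowest adjusted p = 0.941, 37 of the 133 at an unadjusted p below 0.05). The cause of these moves was not tested.

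The labels state no pairing, and the replicate numbers gave no clear sign of one, though a check over 4 pairs cannot settle it. Same-numbered libraries correlated at -0.119 to 0.234 in their deviations from the group means, above 0.1 in 2 of 4 pairs, and 2 of 4 vehicle libraries correlated best with their own number. With the replicate number as a block, 686 genes were called, 552 of them among the 770 and all 552 in the same direction. The block gave 20 lists and 167 terms, and ended the call of 6 genes of the named set and added 6. Those ended were Ceacam2 (adjusted p = 0.0538), Ms4a1 (0.0568), Bpgm (0.0573), Reg1 (0.0574), Mvd (0.0642) and Msi1 (0.0701).

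The sign of 15 results turned in some alternative, 6 lists and 9 genes, 0 of them called before, and the cause was not tested. Values are list medians or log2 fold changes. Tuft cells turned with no filter (-0.12) and irinotecan handling with limma-voom (-0.037). With quality weights, goblet cells (-0.22), tuft cells (-0.051), fatty acid oxidation (-0.034), ribosomal proteins (-0.027), Gp2 (0.50) and Ceacam1 (0.22) turned. With the length trend removed, goblet cells (-0.050), tuft cells (-0.047), ribosomal proteins (-0.13), Casp1 (-0.0055) and Rpl27 (-0.060) did. Without CPT-11 replicates 2 and 4, goblet cells (-0.32), ribosomal proteins (-0.23) and Ceacam1 (0.53) turned and passed, and enteroendocrine cells (-0.044), tuft cells (-0.24), Tff3 (-0.11), mt-Atp6 (-0.073), Rpl7 (-0.11), Rpl27 (-0.059), Rpl14 (-0.16) and Gp2 (0.11) turned without passing. With 1 library left out, the range was -0.068 to 0.24 for goblet cells, -0.042 to 0.31 for enteroendocrine cells, -0.093 to 0.17 for tuft cells, -0.0040 to 0.36 for ribosomal proteins, -0.037 to 0.33 for Top1, -0.72 to 0.065 for Gp2 and -0.39 to 0.34 for Ceacam1.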

Other observations

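Tests of list means over libraries were chosen after the lists had been examined. Averaging log2 CPM over each list gives a value per library that does not treat genes as replicates. Of the 29 lists, 13 did not overlap between the groups, 9 higher and 4 lower with CPT-11, where chance gives 2.86% of lists. Each of these had an exact two-sided permutation p of 0.0286, the smallest that 4 against 4 allows, and an adjusted p of 0.0637, so 0 passed after adjustment. With that smallest p, no list could pass unless more lists had separated fully, so the failure says little about any 1 list. Among the 4 lower was the inflammasome list, though 14 of its 22 tested members had a positive fold change. The p53 target mean was 3.47 ± 0.0459 log2 CPM with vehicle and 4.66 ± 0.185 with CPT-11 (n = 4 each). The defence list was at 4.15 ± 0.142 and 5.22 ± 0.0603, and the mitosis list at 5.42 ± 0.144 and 4.71 ± 0.167.

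Several terms outside the fixed lists passed as well. Wnt-protein binding was lower, with 3 of 23 genes down and 1 up (camera adjusted p = 0.00253), and the canonical Wnt signaling pathway had 4 of 45 down and 0 up (0.0118). With an estimated correlation their unadjusted p was 0.0863 and 0.136. Phagosome genes were higher, with 5 of 137 up and 0 down (0.000443, and an unadjusted p of 0.0361 with an estimated correlation). After adjustment each of these stood at 0.941 with an estimated correlation, so these calls were lost.

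Regrouping argues against chance as the source of the gene counts but cannot exclude it, since 1 of 35 splits is the least this design allows. Every other split mixes the treatment groups, so a difference between them adds to the spread within each side. Of the 35 splits of the 8 libraries into 4 and 4, only the real one (1 split) gave 770 genes, and 1 gave 423 genes changed over 2-fold, the lowest number of splits possible, while the highest count of any other split was 0 for both by edgeR. At an unadjusted p below 0.05 the other splits gave 61 to 2164 genes, against 3442 for the real one, and no other tool was run on them. For the lists, 4 splits, the real one included, gave at least the 20 lists of the real one, up to 21. The others of these kept 3 vehicle libraries on the same side, so part of the treatment difference stayed in them. Regrouping therefore does not argue against chance for the lists and cannot decide the question. For the annotation terms it does not argue against chance either, since 25 splits gave at least 133, up to 360. A split with 2 libraries of each group on each side gave 248.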
